A study of Caenorhabditis elegans with 3 samples.

How the data were processed

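Motor neurons were profiled by droplet-based 3′ single-cell RNA sequencing (10x Genomics) in 3 libraries, replicates 1 to 3 of the unc-3 mutant group. Per the labels, the animals carried unc-3(n3435) and a lin-39 promoter RFP reporter, and were dissociated as young adults before cells were sorted by fluorescence. The labels speak of GFP-positive cells although the reporter they name is RFP, so the sorted signal is uncertain. The deposited matrices hold UMI counts per gene and cell, whole numbers that the authors neither scaled nor normalized. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.1, and per the file headers the gene models were those of WormBase WS273 with 3′ ends extended. The percent of UMIs from the mitochondrial genome, the cell type, the anatomical class and the split into neurons and other cells are the authors' deposited values for each cell. Filters on cells, ambient RNA handling, doublet calling and clustering by the authors are not given in the sources used here. The matrices also hold 2 libraries, wild type by their names, that are not among the samples of the study record analysed here. These were left out of every step, so nothing was compared with the wild type.

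The matrix of all cells held 15984 genes and 25647 cells with 31049777 UMIs in the 3 libraries. The motor neuron matrix held 11155 genes and 9682 cells with 11166860 UMIs, between 60 and 8184 UMIs per cell, and 3 of its cells carried a non-neuronal tag and were kept with their class. The matrix totals made up 99.94% of the deposited totals per cell. The highest mitochondrial share was 19.9%. No doublet caller was run, and only cells with at least 1% of UMIs from unc-25 on the cholinergic side were checked. Coordinates are 1-based positions in the WS273 gene models.

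UMI counts were summed per library and annotated class, and classes with 20 or more cells in each library were kept. The GABAergic side was DD and VD. The cholinergic side was AS, VC and the 3 clusters that the authors annotated as motor neurons of the mutant without a class name. Placing those clusters on the cholinergic side is an assumption made here, which the annotation does not state. Each comparison was tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr, and Benjamini-Hochberg adjusted p under 0.05. The library was a block, because all classes of a library come from the same animals, dissociation, sort and run, which is where the pairing of same-numbered sums comes from. Log2 fold changes are GABAergic minus cholinergic, DD minus VD, or a class minus the mean of the log2 levels of the other classes. Standard errors were back-calculated from that fit, as the absolute log2 fold change over the square root of the F statistic of the test. They therefore restate the test and are not errors that the fit gives for its coefficients. The common biological coefficient of variation was 0.141 for GABAergic against cholinergic neurons, 0.153 for DD against VD and 0.168 for the fit of cholinergic classes. Between libraries, correlations of log levels within a class, across genes above a minimum mean level, ran from 0.542 to 0.966. Genes are not independent replicates. Unnamed cluster 3 had the lowest values, 0.542, 0.619 and 0.624, and the other classes ran from 0.835 to 0.966.

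Levels are counts per 1000000 UMIs of a class sum (CPM). Where a side had no count, the fold is a lower bound against 3 counts over that side. With 1 to 3 counts, the ratio of counts is given with an exact 95% interval. Intervals of class shares are exact Clopper-Pearson intervals, and intervals and floors cover counting error only. Gene lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, on voom values (limma 3.58.1). The lists were acetylcholine genes, reported UNC-3 targets, GABA genes, D-type identity, VC identity, Hox genes, panneuronal genes, monoamine genes, glutamate release, acetylcholine receptors, GABA receptors, glutamate receptors, neuropeptides, innexins, tandem-pore potassium channels, DEG/ENaC channels, homeobox genes, nuclear hormone receptors, axon guidance, synaptic organizers, ribosomal proteins, mitochondrial genome, heat-shock proteins, neuronal stress, and markers of body muscle, pharyngeal muscle, hypodermis, intestine, germline, sperm, coelomocytes, glia and other neurons. Lists were written from general knowledge of the genes and not from these libraries.

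Genes named in the text followed a rule. Among genes past the threshold with a mean of 100 CPM or more on the higher side and the same direction in 3 of 3 libraries, the 12 with the largest positive and negative changes were eligible for GABAergic against cholinergic neurons, and 8 for the other comparisons. Members of the acetylcholine, UNC-3 target, GABA, D-type, VC and Hox lists were eligible in the first comparison, with the most abundant passing members of the other lists, unc-3 and lin-39. The comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except for those named in the closing section as added later. The class levels of unc-54 and the genes it was tested with were chosen after their values were seen.

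Alternatives were DESeq2 1.42.0 in place of edgeR, median-ratio scaling, library size scaling only, no low-count filter, leaving out each replicate in turn, no replicate block, cells with 1000 or more UMIs, cells with under 10% mitochondrial UMIs, and thinning to equal cells and UMIs. Further alternatives left out VC, the unnamed clusters, unc-25-rich cells or unc-54, gave equal weight to each class, or asked for a change of 2-fold or more. The gene-level tests of the 7 comparisons were tested on simulated data, in which 200 genes per comparison were changed. The changed genes were drawn only from genes above a minimum mean count, as many raised as lowered. No other systematic difference between classes or libraries was simulated, apart from depth and scaling. Recovery in genes with few counts was thus not simulated, nor were data like these, in which 14.2 to 50.7% of genes passed. The gene list tests and the other steps were not simulated. The shares of 2-fold and 4-fold changes recovered were 78 and 99.0% for GABAergic against cholinergic neurons (6327 genes), 77 and 100% for DD against VD (4665 genes), 82 and 100% for AS (3569 genes), 90 and 99% for VC (3552 genes), 87 and 99% for unnamed cluster 1 (3518 genes), 83 and 99% for unnamed cluster 2 (3604 genes) and 45 and 85% for unnamed cluster 3 (3540 genes). In the same order, false calls made up 6.38, 5.35, 3.19, 1.05, 5.58, 4.71 and 5.80% of the calls, above 5% in 4 of the 7. Up to 100 other splits of the class sums were drawn per comparison with a fixed seed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.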

Results

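Single-cell transcriptomes were collected from 3 libraries of motor neurons sorted from young adult C. elegans carrying unc-3(n3435), grown for 62 to 65 hours from the first larval stage. UNC-3 is a transcription factor of the COE family, a terminal selector of cholinergic motor neuron identity. All 3 libraries belonged to the unc-3 mutant group, so comparisons were made between classes of neurons inside each library. The libraries held 8380, 9620 and 7647 annotated cells with 10766000, 12939785 and 7343992 UMIs. Motor neurons of the ventral nerve cord numbered 2639, 2904 and 4139 per library and carried 4021340, 4305290 and 2840230 UMIs, with medians of 1442, 1425.5 and 622 UMIs per cell. A count of 0 in the motor neurons of a library allows up to 0.746, 0.697 and 1.06 counts per 1000000 UMIs (CPM). Levels are given as the mean CPM ± SD over 3 libraries, and changes as log2 fold change ± SE with n = 3 libraries per class. Named changes had the same direction in 3 of 3 libraries unless stated.

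Transcripts of the mutated gene were read first. The unc-3 gene (WBGene00006743, chromosome X, 14773538 to 14783564 in the WS273 gene models, plus strand, 12 exons) was detected at 348 ± 170 CPM in the AS class, from 558 UMIs. Levels were 154 ± 73.2 CPM in unnamed cluster 2, 116 ± 38.3 in unnamed cluster 3 and 78.5 ± 35.7 in unnamed cluster 1, the 3 clusters that the authors annotated as motor neurons of the mutant without a class name. In VC neurons, which innervate vulval muscle, unc-3 reached 3.53 ± 6.12 CPM from 3 UMIs. In the GABAergic classes it reached 3.43 ± 2.04 CPM in DD from 7 UMIs and 0.316 ± 0.547 CPM in VD from 1 UMI. Cells with at least 1 unc-3 UMI made up 25.7% of AS cells, at a median depth of 1017 UMIs, and 0.0324% of VD cells, at a median depth of 1061 UMIs. Over replicates 1, 2 and 3 the AS share was 41.4, 33.5 and 8.79%, at median depths of 1283, 1172 and 595 UMIs. The AS level was 485, 402 and 159 CPM in the same order. The read position relative to the n3435 lesion is not given, and the 3′ untranslated region spans 14783046 to 14783564, so the transcript level checks neither the genotype nor the labels.

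GABAergic neurons made up 48.3 ± 0.65% of the motor neurons (SD, n = 3 libraries) and the other classes 51.7 ± 0.65%. Those others, AS, VC and the 3 unnamed clusters, are called the cholinergic side here. The annotation does not call the unnamed clusters cholinergic, so placing them on that side is an assumption. VD neurons were the most frequent class at 31.7 ± 1.45%, and DD neurons made up 16.6 ± 1.41%. On the cholinergic side, unnamed cluster 1 held 18.9 ± 4.21% and AS 15.3 ± 4.20% of the cells. Unnamed cluster 2 followed with 9.26 ± 1.5%, VC with 6.85 ± 2.23% and unnamed cluster 3 with 1.46 ± 0.297%. The deposited annotation named no DA, DB, VA or VB cell in these libraries. Shares depended on depth. Among cells with 1000 or more UMIs, the mean VC share was 12.8%, with 5.80, 11.2 and 21.3% in replicates 1, 2 and 3, and the mean DD share was 20.1%. The mean VD share was 24.3%, with 31.2 and 36.3% in replicates 1 and 2 and 5.29% in replicate 3, so the lower mean rests on replicate 3. The median share of mitochondrial UMIs was 0 in VC in each library and 0.358, 0.370 and 0.411% in AS in replicates 1, 2 and 3. It varied more between libraries in unnamed cluster 1 (0.1186, 0.858 and 0.213%) and in VD (0.135, 0 and 0.566%). Cells with at least 1% of UMIs from unc-25, a transcript of GABAergic neurons, numbered 13 of 5007 on the cholinergic side (0.26%), against a median share of 4.67% of UMIs in GABAergic cells. Neurons made up 46.1, 57.0 and 78.1% of all cells in the libraries labelled replicate 1, 2 and 3, and 9 of 16 non-neuronal cell types had no cell in replicate 3.

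**Figure D1:**
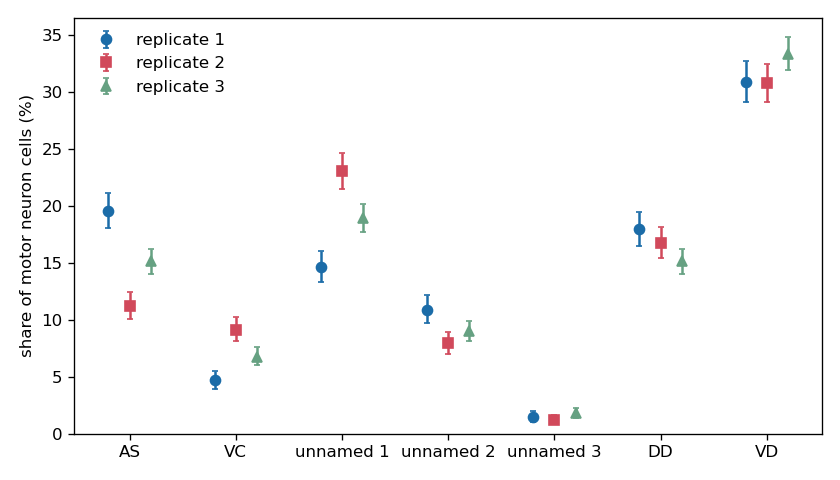
Share of each annotated class among the motor neurons of each unc-3 mutant library, in percent of cells, with points for the 3 libraries. Bars are the exact Clopper-Pearson interval of each library, which covers counting error only and not the spread between libraries. By the mean over libraries, which is not drawn, VD was the most frequent class at 31.7% and unnamed cluster 3 the least frequent at 1.46%.

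The first comparison asked which genes set GABAergic motor neurons (DD and VD summed) apart from the cholinergic side (AS, VC and the 3 unnamed clusters summed) in unc-3 mutant animals. GABAergic neurons carried the genes of GABA synthesis and release. The glutamate decarboxylase gene unc-25 (WBGene00006762, chromosome III, 12942333 to 12949947) reached 59609 ± 26335 CPM against 74.8 ± 42.5 CPM on the cholinergic side (log2 fold change 9.38 ± 0.67, adjusted p = 2.11e-05, higher in 3 of 3 libraries). The vesicular GABA transporter gene unc-47 was higher by 2.59 ± 0.13, and unc-46, which directs that transporter to synaptic vesicles, by 4.95 ± 0.13. Their homeobox regulator unc-30 (WBGene00006766, chromosome IV, 13119090 to 13124390) reached 2353 ± 666 CPM against 6.19 ± 2.98 CPM (8.32 ± 0.26). Among the genes that set the cholinergic side apart were the neuropeptide genes flp-28 and nlp-6, read mainly in VC. The FMRFamide-related gene flp-28 reached 19448 ± 7871 CPM over the summed side against 7.11 ± 10.2 CPM in GABAergic neurons (-12.05 ± 0.60). By class it reached 99440 ± 29930 CPM in VC and 8440 ± 8124 in unnamed cluster 3, against 676, 134 and 379 CPM in AS and unnamed clusters 1 and 2. The gene nlp-6 differed by -11.07 ± 0.67, with 76190 ± 16770 CPM in VC and 11750 ± 6693 in unnamed cluster 3. Because the authors annotated the classes from the same transcriptomes, genes that define a class are not independent evidence of a difference.

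Acetylcholine genes were read mainly on the cholinergic side, and there mainly in VC neurons. The vesicular acetylcholine transporter gene unc-17 reached 174 ± 76.5 CPM on the cholinergic side, a count ratio of 967 (95% interval 173 to 38244) over GABAergic neurons. The choline acetyltransferase gene cha-1 reached 52.1 ± 29.9 CPM, a count ratio of 148 (95% interval 40.6 to 1226), and the choline transporter gene cho-1 64.7 ± 27.5 CPM, a count ratio of 181 (95% interval 49.7 to 1496). The acetylcholinesterase gene ace-2 differed by -1.99 ± 0.56 (adjusted p = 0.0205) and no longer passed without replicate 1 (-1.63). Most UMIs of unc-17, cha-1 and cho-1 came from VC neurons. There unc-17 reached 764 ± 228 CPM, against 75.6 ± 31.5 in AS, 30.3 ± 37.7 in unnamed cluster 3, 6.22 ± 2.43 in unnamed cluster 1 and 2.50 ± 2.32 in unnamed cluster 2. The cho-1 level was 314 ± 101 CPM in VC and 177 ± 118.8 in unnamed cluster 3, against 0.853 ± 1.48 in AS and 0.405 ± 0.702 in unnamed cluster 1. The cha-1 level was 190 ± 99.9 CPM in VC and 53.1 ± 30.5 in unnamed cluster 2, and 0.405 ± 0.702 in unnamed cluster 1. Conversely, unc-47 reached 229 ± 60.3 CPM in unnamed cluster 1 and 195 ± 64.6 in AS, against 3.49 ± 3.47 in VC and 1177 ± 58.7 in VD.

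**Figure D2:**
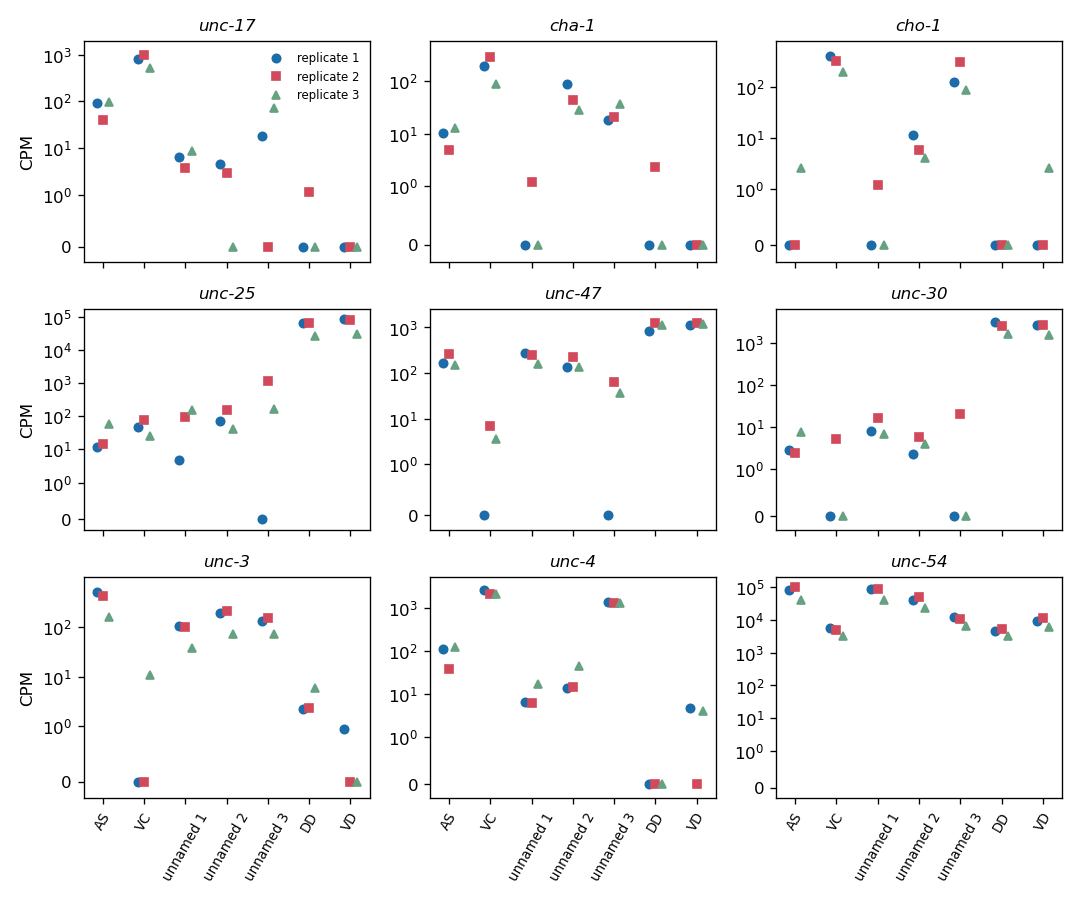
Level of 9 genes in each class, in CPM on an axis that is logarithmic except near its lower end, with points for the 3 libraries. The acetylcholine gene unc-17 is highest in VC at 764 CPM, and the muscle myosin gene unc-54 is highest in AS and unnamed cluster 1.

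Reported UNC-3 targets went both ways. Of 17 tested, 13 were lower in GABAergic neurons and 3 higher. The homeobox gene unc-4 (-8.53 ± 0.40), the channel gene del-1 (-0.61 ± 0.19), the acetylcholine receptor gene acr-2 and the homeobox gene vab-7 were among those lower, acr-2 with a count ratio of 59.6 (95% interval 20.1 to 291) and vab-7 with a count ratio of 418 (95% interval 115 to 3459) toward the cholinergic side. By class, unc-4 and vab-7 were read mainly in VC, where unc-3 had 3 UMIs, and del-1 mainly in AS (161 ± 39.7 CPM). In AS unc-4 reached 89.7 ± 46.1 CPM and vab-7 1.46 ± 2.52. In unnamed cluster 2 they reached 24.4 ± 17.8 and 134 ± 66.9 CPM. The summed side therefore does not show that targets were read in each of its classes. The receptor gene acr-12 (1.29 ± 0.15), the ARID-domain gene cfi-1 (3.75 ± 0.17) and the secreted organizer gene madd-4 (1.51 ± 0.12) were higher. The T-box gene mab-9 did not pass (0.25 ± 0.12, adjusted p = 0.130). The potassium channel gene slo-2 (-0.69 ± 0.14) was lower in 2 of 3 libraries. The signs of del-1, mab-9 and slo-2 depended on which cells were summed, and del-1 was at 0.012 among cells with 1000 or more UMIs and at -0.36, no longer past the threshold, without replicate 1. All 11 D-type identity genes tested were higher in GABAergic neurons, including the ligand-gated channel gene lgc-46, the immunoglobulin-domain gene oig-1 (6.59 ± 0.24), flp-13 (4.46 ± 0.64) and the homeobox gene alr-1 (7.66 ± 0.26). Of 9 VC identity genes tested, 7 were lower, including the LIM homeobox gene lin-11 (-7.92 ± 0.39) and the secretory granule gene ida-1 (-1.49 ± 0.11).

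The Hox gene lin-39, whose promoter drives the RFP reporter of the strain, was lower in GABAergic neurons (-2.13 ± 0.11), as was mab-5 (-0.73 ± 0.13, and 0.15 with equal weight to each class), whereas ceh-13 was higher (1.34 ± 0.12). The gene unc-3 itself was lower by 6.86 on the log2 scale (SE 0.31). Outside these lists, the largest increases in GABAergic neurons included C34B2.9 (WBGene00016394, chromosome I, 10699562 to 10705131), with 147 ± 26.6 CPM against 0 counts and a difference of at least 277-fold, and the chemoreceptor-family gene str-155 (at least 233-fold). The transthyretin-related gene ttr-39 was higher by 9.09 ± 0.25 and the neuropeptide gene nlp-78 by 8.42 ± 0.30. The homeodomain gene dve-1 had a count ratio of 464 (95% interval 158 to 2252). On the cholinergic side the neuropeptide gene flp-3 was at least 2814-fold higher, C50F4.9 at least 511-fold, T14G8.4 at least 509-fold and the touch-neuron tubulin gene mec-7 at least 278-fold. E04D5.5 (WBGene00008484, chromosome II, 10411289 to 10412670) had a count ratio of 7248 (95% interval 2480 to 35150) in the same direction, and nlp-62 a count ratio of 2651 (95% interval 475 to 104761). Of these, flp-3, T14G8.4, E04D5.5 and nlp-62 were read mainly in VC, and mec-7 in AS and unnamed cluster 1. In unnamed cluster 3 mec-7 reached 258 ± 212 CPM from 39 UMIs, against 277 ± 170 CPM in AS. The bounds rest on a floor of 3 counts over the 3 libraries of the side without counts.

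Among transmitter receptors, 11 of 14 acetylcholine receptor subunit genes were higher in GABAergic neurons, including lev-1 (6.38 ± 0.22), acr-9 (6.55 ± 0.23) and des-2 (7.42 ± 0.26). Of 9 glutamate receptor genes tested 8 were lower, including nmr-2 (-7.39 ± 0.29), glc-4 (-6.55 ± 0.45) and avr-14 (-3.67 ± 0.30). The GABA receptor gene unc-49 was higher (5.42 ± 0.23) and 5 others, among them gbb-1 (-1.26 ± 0.17) and lgc-38, were lower, lgc-38 with a count ratio of 90.3 (95% interval 24.7 to 751) toward the cholinergic side. Neuropeptide genes were higher for 10 and lower for 52 of 67 tested, with flp-15 (5.25 ± 0.25) higher and flp-9 (-3.76 ± 0.11) lower. Ribosomal protein genes were lower for 72 and higher for 2 of 77, including rpl-38 (-1.45 ± 0.10) and rps-25 (-1.36 ± 0.10). All 6 body muscle markers tested were lower in GABAergic neurons, led by the myosin heavy chain gene unc-54 (-3.06 ± 0.13) and the tropomyosin gene lev-11 (-1.02 ± 0.24), and 6 of 7 hypodermis markers were lower, including col-20 (-1.94 ± 0.34). The labels do not give the 3′ end of the lin-39 reporter, so reads of reporter transcript among those of unc-54 are not excluded. Stress genes of neurons were higher for 4 of 5, including the kinase gene dlk-1 (0.84 ± 0.16) and cebp-1 (0.88 ± 0.12).

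Counts of genes higher and lower in GABAergic neurons in the remaining lists were Hox genes 1 and 2 of 3, panneuronal genes 6 and 5 of 16, monoamine genes 0 and 1 of 2, innexins 2 and 3 of 6 and tandem-pore potassium channels 7 and 8 of 17. They were DEG/ENaC channels 3 and 4 of 7, homeobox genes 12 and 11 of 29, nuclear hormone receptors 16 and 10 of 52, axon guidance 10 and 9 of 23 and synaptic organizers 6 and 4 of 13. They were mitochondrial genome 0 and 5 of 12, heat-shock proteins 5 and 4 of 15, germline markers 1 and 0 of 1 and markers of other neurons 0 and 3 of 3. All 4 acetylcholine genes were lower, 4 of 5 GABA genes higher. Adjusted over the list alone, counts were the same except for neuropeptides (10 and 53), axon guidance (10 and 10) and heat-shock proteins (6 and 4). As sets with a preset correlation of 0.01, genes of GABA synthesis, D-type identity, acetylcholine receptors and neuronal stress moved up. Acetylcholine, UNC-3 target, VC identity, glutamate receptor, neuropeptide, ribosomal, body muscle and other-neuron genes moved down, with adjusted p = 1.39e-20 for ribosomal proteins. With an estimated correlation every one of these was lost, at adjusted p = 0.511 with an estimated correlation, except for acetylcholine receptors (0.539) and UNC-3 targets (0.634), lost as well. Median, mean and test differed in sign for panneuronal genes, innexins, tandem-pore potassium channels, DEG/ENaC channels and axon guidance.

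In all, 3316 of 6535 genes tested passed adjusted p under 0.05 in the edgeR quasi-likelihood test with library as a block, 1563 higher and 1753 lower in GABAergic neurons. A change of 2-fold or more was seen for 1070 and 1179 genes. The higher share was 47.1% with TMM scaling and 60.6% with library size alone (2002 and 1304 genes), under which the median of all genes moved by 0.25, so small changes depended on the scaling. Under that scaling 66 ribosomal protein genes were lower and 2 higher. With the unnamed clusters left out of the cholinergic side, 2700 genes passed. With library as a block, p-values measure how the difference between classes varied over these libraries, and not the spread of levels between libraries. Nothing in the labels states that the libraries came from separate cultures, so p-values do not extend to a spread between cultures.

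**Figure D3:**
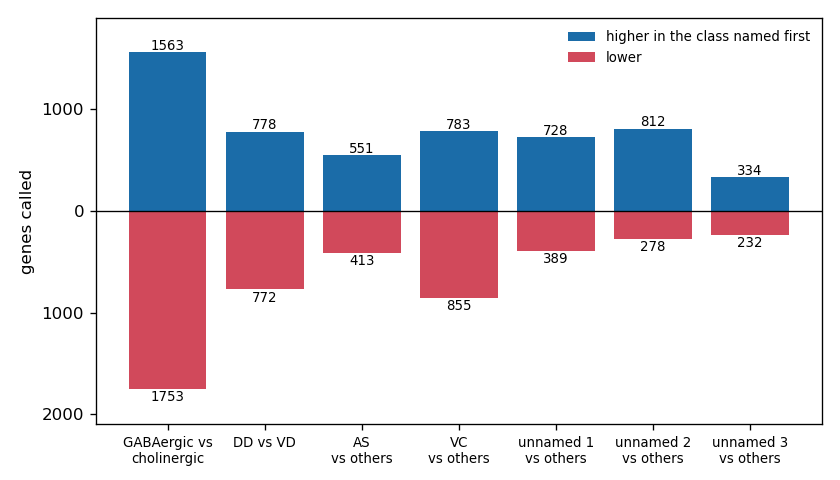
Number of genes past adjusted p under 0.05 that were higher and lower in the first-named side of each comparison, with TMM scaling. The split is 1563 and 1753 genes for GABAergic against cholinergic neurons with TMM scaling.

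The second comparison asked what separates DD from VD, the GABAergic classes that innervate dorsal and ventral body muscle in the adult. DD neurons carried the Iroquois homeobox gene irx-1 (WBGene00007984, chromosome I, 9536465 to 9540966) at 249 ± 90.0 CPM, a count ratio of 390 (95% interval 108 to 3231) over VD. The channel gene del-1 was at least 112-fold higher in DD, with 117 ± 39.96 CPM against 0 counts. The neuropeptide genes flp-14 (7.51 ± 0.16) and flp-13 (4.44 ± 0.18) were also higher in DD, flp-13 at 646 ± 251 CPM against 27.1 ± 9.89. VD neurons carried the nuclear receptor gene unc-55 (WBGene00006790, chromosome I, 7898434 to 7903334), a regulator of VD identity, at 614 ± 119.2 CPM against 27.4 ± 7.88 CPM in DD (-4.57 ± 0.20, adjusted p = 2.19e-07, lower in DD in 3 of 3 libraries). The immunoglobulin-domain gene oig-1 reached 4132 ± 1643 CPM in VD against 421 ± 140 CPM in DD (-3.41 ± 0.16). Other large differences were W05E10.5 (7.77 ± 0.26), T19D12.6 (7.04 ± 0.36) and the secreted Frizzled-related gene sfrp-1, with a count ratio of 231 (95% interval 63.5 to 1916), all higher in DD. Higher in VD were C34B2.9 (-7.18 ± 0.31), str-155 (-5.31 ± 0.37), hot-9 (-4.99 ± 0.18), lntl-1 (-4.34 ± 0.16), iglr-1 (-4.22 ± 0.31) and msp-55 (-6.19 ± 0.29). Whether reads of msp-55 can be separated from those of near-identical sperm protein genes was not tested. The Hox genes lin-39 (-0.93 ± 0.16) and ceh-13 (-0.85 ± 0.15) were lower in DD.

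Of 5 genes of GABA synthesis and transport tested, 2 passed, both lower in DD. In DD unc-25 differed by -0.40 ± 0.08 and unc-46 by -1.23 ± 0.14, and unc-25 no longer passed without replicate 1 (-0.35). Panneuronal genes were lower in DD for 6 and higher for 1 of 16 tested, including the synaptotagmin gene snt-1 (-0.58 ± 0.12) and the syntaxin gene unc-64 (-1.03 ± 0.13). All 11 mitochondrial genome genes tested were lower in DD, including nduo-6 (-3.27 ± 0.36). Counts higher and lower in DD, of those tested, were reported UNC-3 targets 1 and 2 of 6, GABA synthesis and transport 0 and 2 of 5, D-type identity 2 and 6 of 11, VC identity 1 and 0 of 2, Hox genes 0 and 2 of 3 and monoamine genes 1 and 0 of 1. Next came acetylcholine receptor subunits 2 and 2 of 11, GABA receptors 0 and 2 of 2, glutamate receptors 0 and 0 of 1, neuropeptides 8 and 6 of 20, innexins 2 and 0 of 6 and tandem-pore potassium channels 0 and 4 of 9. Further counts were DEG/ENaC channels 2 and 0 of 5, homeobox genes 3 and 5 of 18, nuclear hormone receptors 5 and 17 of 40, axon guidance 6 and 4 of 18, synaptic organizers 1 and 4 of 11 and ribosomal proteins 0 and 18 of 76. Last came heat-shock proteins 3 and 0 of 14, neuronal stress 0 and 1 of 5, body muscle markers 0 and 2 of 2, germline markers 1 and 0 of 1 and markers of other neurons 0 and 1 of 1. Adjusted over the list alone, counts differed only for D-type identity (3 and 7), panneuronal genes (1 and 7), acetylcholine receptor subunits (2 and 3), neuropeptides (8 and 8), nuclear hormone receptors (6 and 17), axon guidance (7 and 4), synaptic organizers (1 and 5) and ribosomal proteins (0 and 10). As sets, heat-shock proteins moved up and GABA synthesis and transport, D-type identity, panneuronal genes, tandem-pore potassium channels, nuclear hormone receptors, synaptic organizers, ribosomal proteins and mitochondrial genome moved down, at preset-correlation adjusted p from 7.07e-06 (mitochondrial genome) to 0.0422. Every one of these was lost with an estimated correlation: adjusted p = 0.549 with an estimated correlation for GABA synthesis and transport, D-type identity, panneuronal genes, tandem-pore potassium channels, nuclear hormone receptors, synaptic organizers and mitochondrial genome, adjusted p = 0.634 with an estimated correlation for heat-shock proteins, adjusted p = 0.649 with an estimated correlation for ribosomal proteins. Median, mean and test of a list differed in sign for reported UNC-3 targets, neuropeptides, DEG/ENaC channels and homeobox genes.

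Of 4816 genes tested, 1550 passed, 778 higher and 772 lower in DD, and 502 and 378 changed 2-fold or more. With library size scaling alone the higher share was 62.2% (932 and 566 genes) in place of 50.2%, and the median of all genes moved by 0.13. The ribosomal list then had 3 genes higher and 9 lower in DD, and the sign of the homeobox median changed. Without replicate 1 the count was 956, and with DESeq2 it was 966.

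The remaining comparisons asked which genes still separate the classes of the cholinergic side, called cholinergic classes here, from each other in these animals. Each class was set against the mean of the log2 levels of the other 4 classes, in 1 fit of 3982 genes. VC neurons lie far above the other classes for some genes and far below them for others, such as unc-3. The log2 changes are also TMM-scaled, while the plain means are not. The sign of a difference of mean log2 levels and that of plain means can therefore differ. They did so for 20 of 964 genes in AS, 8 of 1638 in VC, 62 of 1117 in unnamed cluster 1, 43 of 1090 in unnamed cluster 2 and 15 of 566 in unnamed cluster 3. For every gene that follows both had the same sign unless stated. A low level in VC also lowers the mean log2 level that each other class is set against. A gene can then pass as higher in several of those classes, as mitochondrial genome genes did. Count ratios and folds written as at least a value compare the class with the summed counts of the other 4 classes, another quantity than the difference of mean log2 levels.

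AS neurons, which innervate dorsal body muscle, were marked by osm-11, a gene for a secreted Notch ligand (WBGene00003891, chromosome X, 17420168 to 17421582). It reached 7206 ± 3024 CPM against 61.8 ± 55.4 CPM over the other classes (9.46 ± 0.50, adjusted p = 2.17e-10, higher in 3 of 3 libraries). The gene C12D8.15 (WBGene00007542, chromosome V, 10228641 to 10229322) reached 774 ± 392 CPM in AS, a count ratio of 3554 (95% interval 637 to 140485) over the other classes, and the neuropeptide gene nlp-38 differed by 7.54 ± 0.26. The carboxylesterase gene cest-3 was at least 145-fold higher and the patched-related gene ptr-23 had a count ratio of 518 (95% interval 142.3 to 4293). Lower in AS were the neuropeptide genes nlp-63 (-6.86 ± 0.33), flp-2 (-5.99 ± 0.43) and nlp-62 (-5.77 ± 0.55), and flp-12 had a count ratio of 268 (95% interval 74.0 to 2214) toward the others but did not pass without replicate 2 (-6.07). The muscle myosin gene unc-54 reached 73210 ± 30320 CPM in AS, 1.88 ± 0.10 above the other classes, and unc-3 was 2.88 ± 0.24 above. Transcripts of unc-17 were 1.48 ± 0.39 above the mean log2 level of the other classes, although its plain mean over them was higher because of VC, and did not pass without replicate 1 (1.46). Of the 116 unc-17 UMIs in AS, 86 came from the annotated subclass AS9_10. Among the Hox genes mab-5 was higher (1.82 ± 0.20) and lin-39 lower (-0.78 ± 0.15, not past the threshold without replicate 1 at -0.56). Both class levels mix unlike subclasses. The lin-39 level ran from 3.95 CPM in AS2_3 to 1575 in AS4_8, and mab-5 from 15.8 CPM in AS2_3 to 610 in AS9_10. All but 1 of the 12 mitochondrial genome genes were higher, including nduo-6 (1.67 ± 0.20), and 17 of 77 ribosomal protein genes were higher and 0 lower.

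In AS 964 genes passed, 551 higher and 413 lower. Without replicate 1 the count was 633. List by list, genes higher and lower in AS, of those tested, were acetylcholine synthesis, transport and breakdown 1 and 1 of 4, reported UNC-3 targets 4 and 7 of 15, GABA synthesis and transport 1 and 1 of 4, D-type identity 2 and 2 of 5, VC identity 0 and 3 of 9, Hox genes 1 and 1 of 3 and panneuronal genes 3 and 1 of 16. Next came monoamine genes 0 and 0 of 2, glutamate release 0 and 0 of 1, acetylcholine receptor subunits 1 and 0 of 5, GABA receptors 2 and 1 of 5, glutamate receptors 1 and 2 of 8, neuropeptides 17 and 20 of 56 and innexins 0 and 1 of 6. Further counts were tandem-pore potassium channels 2 and 2 of 12, DEG/ENaC channels 2 and 1 of 3, homeobox genes 4 and 6 of 20, nuclear hormone receptors 6 and 1 of 24, axon guidance 4 and 1 of 22, synaptic organizers 2 and 3 of 12 and heat-shock proteins 8 and 1 of 13. Last came neuronal stress 0 and 1 of 5, body muscle markers 2 and 0 of 4, hypodermis markers 1 and 0 of 6 and markers of other neurons 1 and 0 of 4. Counts adjusted over the list alone differed only for reported UNC-3 targets (4 and 8), VC identity (1 and 3), neuropeptides (17 and 21), homeobox genes (4 and 7), synaptic organizers (2 and 4) and ribosomal proteins (5 and 0). As sets, ribosomal proteins and mitochondrial genome moved up, at preset-correlation adjusted p from 1.46e-05 (mitochondrial genome) to 4.61e-05. Every one of these was lost with an estimated correlation: adjusted p = 0.496 with an estimated correlation for mitochondrial genome, adjusted p = 0.512 with an estimated correlation for ribosomal proteins. The sign differed between median, mean and test for panneuronal genes, axon guidance and synaptic organizers. Library size scaling changed the sign of the median of the panneuronal and synaptic organizer lists and gave 31 ribosomal genes higher and 0 lower.

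VC neurons carried the highest levels of unc-17, cho-1 and cha-1 among the classes. Against the other classes unc-17 was higher by 5.61 ± 0.27 (adjusted p = 5.14e-12), cho-1 by 5.70 ± 0.27 and cha-1 by 4.16 ± 0.32. The VC identity genes lin-11 (5.86 ± 0.23) and glr-5 (1.19 ± 0.17) and the homeobox genes unc-4 (2268 ± 294 CPM, 4.91 ± 0.19) and vab-7 (6.72 ± 0.28) were higher. The neuropeptide genes nlp-79 (WBGene00008626, chromosome IV, 13149576 to 13150571, 9.71 ± 0.41) and flp-3 (8.55 ± 0.27) led the increases, with flp-28 at 99440 ± 29930 CPM and nlp-6 at 76190 ± 16770 CPM. The arrestin-domain gene arrd-5 had a count ratio of 631 (95% interval 214 to 3069). Lower in VC were pdf-1 (-8.51 ± 0.89), osm-11 (at least 943-fold), the insulin-like gene ins-1 (at least 95.7-fold) and mec-7 (at least 72.0-fold). The osm-11 difference did not pass without replicate 2 (-8.0) or without replicate 3 (-6.47). Genes read as GABAergic were lower too, unc-47 at -4.88 ± 0.55 and unc-46 at -2.16 ± 0.32. The Hox gene lin-39 did not pass (-0.30 ± 0.15, adjusted p = 0.121), and ceh-13 was lower (-2.11 ± 0.26). Lower as well were unc-54 (-3.06 ± 0.14) and unc-3, with a count ratio of 72.4 (95% interval 24.7 to 352) toward the others. All 12 mitochondrial genome genes and 73 of 77 ribosomal protein genes were lower, with 1 ribosomal gene higher.

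In VC 1638 genes passed, 783 higher and 855 lower. Higher and lower in VC, of those tested, were acetylcholine synthesis, transport and breakdown 3 and 0 of 4, reported UNC-3 targets 8 and 2 of 15, GABA synthesis and transport 0 and 2 of 4, D-type identity 0 and 2 of 5, VC identity 8 and 0 of 9, Hox genes 0 and 1 of 3 and panneuronal genes 3 and 4 of 16. Next came monoamine genes 1 and 0 of 2, glutamate release 0 and 0 of 1, acetylcholine receptor subunits 1 and 3 of 5, GABA receptors 3 and 2 of 5, glutamate receptors 4 and 2 of 8, neuropeptides 23 and 19 of 56 and innexins 2 and 0 of 6. Further counts were tandem-pore potassium channels 5 and 3 of 12, DEG/ENaC channels 1 and 0 of 3, homeobox genes 8 and 2 of 20, nuclear hormone receptors 3 and 6 of 24, axon guidance 10 and 8 of 22, synaptic organizers 4 and 1 of 12 and heat-shock proteins 0 and 9 of 13. Last came neuronal stress 0 and 1 of 5, body muscle markers 0 and 2 of 4, hypodermis markers 0 and 4 of 6 and markers of other neurons 0 and 2 of 4. When adjusted over the list alone, counts differed only for VC identity (9 and 0), monoamine genes (2 and 0), glutamate receptors (4 and 3), neuropeptides (23 and 23), synaptic organizers (4 and 2), ribosomal proteins (1 and 74) and markers of other neurons (1 and 2). As sets, acetylcholine synthesis, transport and breakdown, reported UNC-3 targets and VC identity moved up and ribosomal proteins, mitochondrial genome, heat-shock proteins and hypodermis markers moved down, at preset-correlation adjusted p from 6.15e-23 (ribosomal proteins) to 0.0478. Every one of these was lost with an estimated correlation: adjusted p = 0.113 with an estimated correlation for VC identity, adjusted p = 0.153 with an estimated correlation for acetylcholine synthesis, transport and breakdown, reported UNC-3 targets and ribosomal proteins, adjusted p = 0.201 with an estimated correlation for mitochondrial genome, adjusted p = 0.229 with an estimated correlation for heat-shock proteins, adjusted p = 0.348 with an estimated correlation for hypodermis markers. A list median, mean and test differed in sign for glutamate receptors, neuropeptides, DEG/ENaC channels and axon guidance. With library size scaling 883 genes were higher and 782 lower, and with median-ratio scaling 830 and 827, so the majority direction depended on the scaling. With library size scaling 72 ribosomal genes were lower and 1 higher.

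Unnamed cluster 1 was marked by the neuropeptide genes pdf-1 (6643 ± 1278 CPM, 4.57 ± 0.41) and flp-14 (5.99 ± 0.22, adjusted p = 1.40e-12). In it unc-17 was -2.73 ± 0.66 relative to the other classes, and not past the threshold without replicate 1 (-2.65). The genes cho-1 and cha-1 had 1 UMI each, cho-1 with a count ratio of 209 (95% interval 37.3 to 8282) and cha-1 with a count ratio of 171 (95% interval 30.5 to 6782) toward the others, and cho-1 did not pass without replicate 3 (-4.32). The gene W04C9.8 (WBGene00235387, chromosome I, 471135 to 473890) was higher by 6.02 ± 0.46, the proteoglycan gene cpg-9 by 4.53 ± 0.20 and the osteonectin gene ost-1 by 4.08 ± 0.20. Lower were the receptor gene npr-27 (at least 118-fold), flp-28 (-5.21 ± 0.69) and flp-2 (-5.13 ± 0.47), and the zinc finger gene egl-46 had a count ratio of 330 (95% interval 59.0 to 13057) toward the others. The homeobox gene vab-7 had a count ratio of 485 (95% interval 86.9 to 19184) in the same direction. The egl-46 difference did not pass without replicate 1 (-4.38), nor did vab-7 without replicate 1 (-4.14) or without replicate 2 (-3.82). The Hox gene lin-39 was higher (1845 ± 368 CPM, 1.28 ± 0.13) and mab-5 lower (-3.74 ± 0.34). GABA transport genes were higher, unc-47 by 2.57 ± 0.23 and unc-46 by 1.95 ± 0.18. The unc-47 difference rests largely on low levels in VC and unnamed cluster 3. In AS (195 ± 64.6 CPM) and unnamed cluster 2 (169 ± 52.5 CPM) unc-47 was near its level in unnamed cluster 1, and it passed as higher there too. The unc-3 difference of mean log2 levels did not pass (0.51 ± 0.29, adjusted p = 0.219) but did without replicate 3 (1.35), while by plain means unc-3 was lower in the cluster, at 78.5 ± 35.7 CPM against 155 ± 67.4. The gene unc-54 was higher (71160 ± 27140 CPM, 2.15 ± 0.10). Of 15 reported UNC-3 targets 12 were lower and 2 higher, including unc-4 (-4.57 ± 0.36) and madd-4 (-0.73 ± 0.13). Ribosomal protein genes were higher for 75 of 77.

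For unnamed cluster 1, 1117 genes passed, 728 higher and 389 lower. By list, genes higher and lower in the cluster were acetylcholine synthesis, transport and breakdown 0 and 3 of 4, reported UNC-3 targets 2 and 12 of 15, GABA synthesis and transport 2 and 0 of 4, D-type identity 2 and 1 of 5, VC identity 1 and 3 of 9, Hox genes 1 and 1 of 3 and panneuronal genes 1 and 6 of 16. Next came monoamine genes 0 and 0 of 2, glutamate release 0 and 0 of 1, acetylcholine receptor subunits 1 and 2 of 5, GABA receptors 1 and 1 of 5, glutamate receptors 3 and 2 of 8, neuropeptides 13 and 19 of 56 and innexins 0 and 2 of 6. Further counts were tandem-pore potassium channels 0 and 2 of 12, DEG/ENaC channels 1 and 2 of 3, homeobox genes 2 and 6 of 20, nuclear hormone receptors 4 and 1 of 24, axon guidance 2 and 6 of 22, synaptic organizers 0 and 5 of 12 and mitochondrial genome 5 and 0 of 12. Last came heat-shock proteins 3 and 1 of 13, neuronal stress 2 and 0 of 5, body muscle markers 1 and 0 of 4, hypodermis markers 1 and 0 of 6 and markers of other neurons 2 and 0 of 4. List counts adjusted over the list alone differed only for reported UNC-3 targets (2 and 13), acetylcholine receptor subunits (1 and 3), neuropeptides (14 and 22), axon guidance (2 and 7) and mitochondrial genome (6 and 0). As sets, ribosomal proteins and mitochondrial genome moved up and acetylcholine synthesis, transport and breakdown, reported UNC-3 targets, VC identity, panneuronal genes, neuropeptides, innexins, tandem-pore potassium channels, homeobox genes and synaptic organizers moved down, at preset-correlation adjusted p from 2.04e-65 (ribosomal proteins) to 0.0373. UNC-3 targets and ribosomal proteins held at adjusted p = 0.0198 with an estimated correlation. The others were lost, with adjusted p = 0.0524 with an estimated correlation for acetylcholine synthesis, transport and breakdown, adjusted p = 0.0564 with an estimated correlation for tandem-pore potassium channels, adjusted p = 0.0708 with an estimated correlation for synaptic organizers, adjusted p = 0.0839 with an estimated correlation for homeobox genes, adjusted p = 0.105 with an estimated correlation for VC identity, adjusted p = 0.145 with an estimated correlation for innexins, adjusted p = 0.205 with an estimated correlation for panneuronal genes, adjusted p = 0.236 with an estimated correlation for neuropeptides, adjusted p = 0.312 with an estimated correlation for mitochondrial genome. Signs of median, mean and test differed for D-type identity, Hox genes and markers of other neurons. With library size scaling the split was 442 higher and 642 lower, the higher share 40.8% in place of 65.2%, and the median of all genes moved by -0.26. Ribosomal proteins then had 74 genes higher and 0 lower, and the sign of the nuclear hormone receptor median changed.

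Unnamed cluster 2 was marked by the neuropeptide genes nlp-58 (7.35 ± 0.90) and flp-12 (WBGene00001455, chromosome X, 4591281 to 4592404, 1524 ± 723 CPM against 55.3 ± 69.5, 6.32 ± 0.48, adjusted p = 6.83e-09). The genes R13A5.15 (7.45 ± 0.43), K10H10.6 (7.17 ± 0.41) and the transthyretin-related gene ttr-32 (6.54 ± 0.41) were higher as well. Its acetylcholine genes were split. Transcripts of cha-1 lay 2.11 ± 0.42 above the mean log2 level of the others but below their plain mean, which VC raises. Against that plain mean cha-1 was higher in 1 of 3 libraries, and the difference of log2 levels did not pass without replicate 1 (1.33), whereas unc-17 had a count ratio of 74.7 (95% interval 25.5 to 363) toward the other classes. Lower were the neuropeptide gene flp-24 (-4.32 ± 0.70), the carbonic anhydrase-related gene cah-1 (-4.54 ± 0.35) and F40F8.5, with a count ratio of 854 (95% interval 153 to 33755) toward the others. The Hox gene mab-5 was higher (2.48 ± 0.20), while lin-39 did not pass (0.08 ± 0.15, adjusted p = 0.753) and was lower by plain means (1019 ± 124 CPM against 1122 ± 208). The homeobox gene vab-7 lay 3.92 ± 0.38 above the mean log2 level of the others but below their plain mean, at 134 ± 66.9 CPM against 686 ± 190 in VC. The unc-3 level was higher in 2 of 3 libraries (1.59 ± 0.28), unc-4 lower (-3.24 ± 0.36) and cfi-1 higher (2.40 ± 0.47). Panneuronal genes were higher for 9 and lower for 1 of 16, including egl-3 (0.79 ± 0.11) and ric-4 (0.71 ± 0.10).

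For unnamed cluster 2, 1090 genes passed, 812 higher and 278 lower. Without replicate 1 the count was 719. Genes higher and lower in each list were acetylcholine synthesis, transport and breakdown 2 and 1 of 4, reported UNC-3 targets 4 and 2 of 15, GABA synthesis and transport 2 and 0 of 4, D-type identity 1 and 0 of 5, VC identity 1 and 4 of 9, Hox genes 2 and 0 of 3 and monoamine genes 0 and 0 of 2. Next came glutamate release 1 and 0 of 1, acetylcholine receptor subunits 0 and 0 of 5, GABA receptors 2 and 0 of 5, glutamate receptors 4 and 3 of 8, neuropeptides 23 and 11 of 56, innexins 2 and 0 of 6 and tandem-pore potassium channels 5 and 1 of 12. Further counts were DEG/ENaC channels 1 and 0 of 3, homeobox genes 6 and 4 of 20, nuclear hormone receptors 5 and 4 of 24, axon guidance 7 and 4 of 22, synaptic organizers 3 and 1 of 12, ribosomal proteins 0 and 2 of 77 and mitochondrial genome 8 and 0 of 12. Last came heat-shock proteins 9 and 0 of 13, neuronal stress 4 and 0 of 5, body muscle markers 2 and 0 of 4, hypodermis markers 2 and 0 of 6 and markers of other neurons 1 and 0 of 4. Adjusted over the list alone, the counts differed only for reported UNC-3 targets (5 and 2), D-type identity (2 and 0), VC identity (3 and 5), panneuronal genes (11 and 1), monoamine genes (2 and 0), neuropeptides (28 and 14), DEG/ENaC channels (2 and 0), axon guidance (9 and 5), ribosomal proteins (0 and 0), mitochondrial genome (9 and 0) and heat-shock proteins (10 and 0). As sets, panneuronal genes, neuropeptides, mitochondrial genome and heat-shock proteins moved up, at preset-correlation adjusted p from 7.88e-04 (heat-shock proteins) to 0.0413. Every one of these was lost with an estimated correlation: adjusted p = 0.338 with an estimated correlation for panneuronal genes and heat-shock proteins, adjusted p = 0.419 with an estimated correlation for neuropeptides, adjusted p = 0.504 with an estimated correlation for mitochondrial genome. Of the mitochondrial genes, nduo-6 (1646 CPM against 1983) and ctc-1 (782 against 794) lay below the plain mean of the others. Each was higher in 1 of 3 libraries, while ctc-2 and ctc-3 lay above that mean. Differing signs of median, mean and test were seen for GABA receptors, innexins and nuclear hormone receptors. With library size scaling the higher share was 64.5% (691 and 381 genes) in place of 74.5%, and the median of all genes moved by -0.12. The medians of D-type identity, homeobox and nuclear hormone receptor genes then changed sign, and 0 ribosomal genes were higher and 8 lower.

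Unnamed cluster 3, with 145 cells and 157688 UMIs over the 3 libraries, was marked by the zinc finger gene bnc-1 (WBGene00044791, chromosome V, 12275570 to 12277046) at 484 ± 180 CPM against 3.10 ± 2.22 CPM (7.90 ± 0.48, adjusted p = 9.51e-10). The neuropeptide gene flp-32 reached 3205 ± 1355 CPM (8.14 ± 0.55), the insulin-like gene ins-4 was higher by 8.11 ± 0.60 and nlp-14 by 7.23 ± 0.29. It carried unc-4 at 1338 ± 17.9 CPM (3.81 ± 0.24), lin-11 at 473 ± 111 CPM (4.77 ± 0.34) and cho-1 at 4.51 ± 0.49 above the mean log2 level. The gene oig-1 reached 472 ± 338 CPM (5.38 ± 0.30), near its level in DD (421 ± 140 CPM) and below that in VD (4132 ± 1643 CPM). Lower were F38B6.6 (at least 8.62-fold), the ciliary gene dyf-6 (at least 6.84-fold) and the linker histone gene hil-1 (at least 6.57-fold). The dyf-6 difference did not pass without replicate 3 (-6.80), nor did hil-1 without replicate 2 (-6.25) or without replicate 3 (-7.27). The gene K09F6.10 was lower too (-5.22 ± 0.40), as were its neighbours K09F6.9 and K09F6.13. Whether these genes share reads was not tested. Levels of lin-39 (-0.29 ± 0.17, adjusted p = 0.341) and unc-3 (0.76 ± 0.46, adjusted p = 0.340) did not pass, and unc-3 was lower in the cluster by plain means (116 ± 38.3 CPM against 146 ± 67.3). Ribosomal protein genes were lower for 62 of 77, including rpl-12 (-0.95 ± 0.12).

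For unnamed cluster 3, 566 genes passed, 334 higher and 232 lower. The lists split into higher and lower as follows: acetylcholine synthesis, transport and breakdown 2 and 0 of 4, reported UNC-3 targets 7 and 2 of 15, GABA synthesis and transport 1 and 0 of 4, D-type identity 2 and 0 of 5, VC identity 4 and 1 of 9, Hox genes 0 and 0 of 3 and panneuronal genes 2 and 2 of 16. Next came monoamine genes 1 and 0 of 2, glutamate release 1 and 0 of 1, acetylcholine receptor subunits 2 and 0 of 5, GABA receptors 1 and 1 of 5, glutamate receptors 3 and 1 of 8, neuropeptides 23 and 6 of 56 and innexins 1 and 0 of 6. Further counts were tandem-pore potassium channels 2 and 0 of 12, DEG/ENaC channels 1 and 1 of 3, homeobox genes 3 and 0 of 20, nuclear hormone receptors 0 and 0 of 24, axon guidance 5 and 2 of 22, synaptic organizers 4 and 0 of 12 and mitochondrial genome 5 and 0 of 12. Last came heat-shock proteins 0 and 2 of 13, neuronal stress 1 and 2 of 5, body muscle markers 0 and 1 of 4, hypodermis markers 1 and 0 of 6 and markers of other neurons 3 and 1 of 4. The GABA gene that passed was unc-25 (429 ± 608 CPM, 2.44 ± 0.69), higher in 2 of 3 libraries and lost without replicate 2 (0.39). In replicate 2, 2 of the 34 cells of the cluster had at least 1% of UMIs from unc-25. Here counts adjusted over the list alone differed only for VC identity (4 and 2), Hox genes (1 and 0), panneuronal genes (2 and 3), GABA receptors (2 and 1), neuropeptides (25 and 8), axon guidance (6 and 5), ribosomal proteins (0 and 69), mitochondrial genome (6 and 0) and heat-shock proteins (0 and 3). As sets, acetylcholine synthesis, transport and breakdown, reported UNC-3 targets, VC identity, acetylcholine receptor subunits, glutamate receptors, neuropeptides, tandem-pore potassium channels, synaptic organizers and mitochondrial genome moved up and ribosomal proteins moved down, at preset-correlation adjusted p from 5.95e-29 (ribosomal proteins) to 0.0464. Every one of these was lost with an estimated correlation: adjusted p = 0.136 with an estimated correlation for acetylcholine synthesis, transport and breakdown, reported UNC-3 targets, VC identity, acetylcholine receptor subunits, glutamate receptors, neuropeptides, tandem-pore potassium channels, synaptic organizers and ribosomal proteins, adjusted p = 0.269 with an estimated correlation for mitochondrial genome. In this class median, mean and test differed in sign for GABA synthesis and transport, Hox genes, panneuronal genes, tandem-pore potassium channels, DEG/ENaC channels, homeobox genes, nuclear hormone receptors and synaptic organizers. With library size scaling the higher share was 76.3% (438 and 136 genes) in place of 59.0%, the median of all genes moved by 0.23, and 41 ribosomal genes were lower and 0 higher. In simulated data with 3540 genes, only genes above a minimum mean count were changed. The test recovered 45% of 2-fold and 85% of 4-fold changes for this class, the lowest shares of the 7 comparisons. Genes that did not pass are therefore not shown to be equal.

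**Figure D4:**
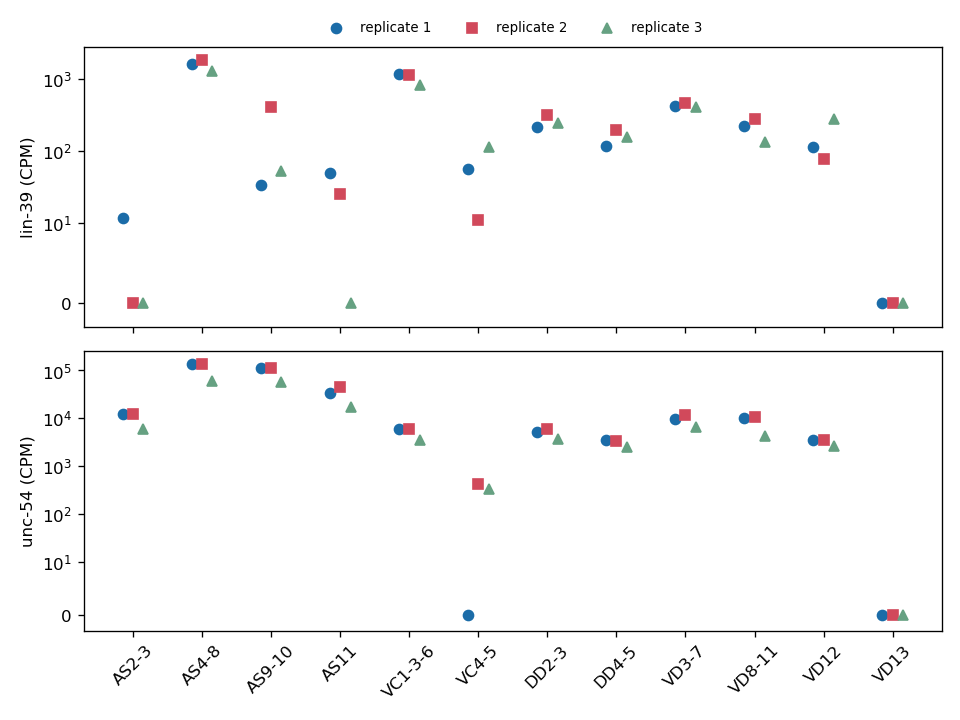
Level of lin-39 and unc-54 in each annotated subclass, in CPM on a logarithmic axis, with points for the 3 libraries. In AS, VC, DD and VD the subclass highest in lin-39 is also highest in unc-54, while AS9_10 carries unc-54 at 94670 CPM with lin-39 at 162.5 CPM and VC1_3_6 carries it at 5112 CPM with lin-39 at 1033 CPM.

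Lists of pharyngeal muscle, intestine, sperm, coelomocyte and glia markers had no gene that passed the count filter in any comparison, and genes of glutamate release had none in the GABAergic comparisons. The acetylcholine and hypodermis lists had none for DD against VD, and germline markers none among the cholinergic classes. The comparisons of A-type with B-type classes and of dorsal with ventral cholinergic classes were not run, because no cell of these libraries was annotated as DA, DB, VA or VB.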

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

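The tests of the patterns in this part were chosen after the patterns were seen.

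Transcripts of 4 genes gave a signal in cells outside the motor neurons compared in the report, above the level that a count of 0 allows. The unc-3 gene was read in ASI sensory neurons at 146 ± 114 CPM (SD, n = 3 libraries, 349 UMIs, at least 20 per library, floor 1.20 CPM). A further neuron cluster of the mutant that the authors left unnamed, and that is not among the motor neurons, carried unc-4 at 528 ± 122.4 CPM (1070 UMIs, at least 213 per library, floor 1.54 CPM). The same cluster carried bnc-1 at 27 ± 6.71 CPM (50 UMIs, at least 16 per library). The cell-death activator gene egl-1 was read there at 56.1 ± 22.6 CPM (117 UMIs, at least 20 per library) and in SDQL neurons at 30.8 ± 8.04 CPM (64 UMIs, at least 14 per library, floor 1.48 CPM). No explanation of these signals was tested.

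The first pattern weighed was the level of the muscle myosin gene unc-54, at 73210 CPM in AS and 71160 CPM in unnamed cluster 1 against 4587 CPM in VC. RNA of body wall muscle cells is excluded, because the highest of unc-15, mup-2, tnt-2 and myo-3 in these classes reached 0.0383% of the level that their ratio to unc-54 in muscle needs. Body wall muscle cells themselves carried unc-54 at only 3389 CPM, pooled over replicates 1 and 2, against 75119 CPM pooled over 3 libraries in AS. Replicate 3 held 0 body wall muscle cells, so the muscle ratios rest on replicates 1 and 2. RNA free in the suspension is excluded as the whole cause too, since unc-54 in these classes was at least 6.32 times its highest level in DD, VD and VC of the same library. A candidate explanation is a lin-39 reporter that ends in the unc-54 3′ end: 4 of the 4 classes with subclasses had most unc-54 in the subclass highest in lin-39, but AS9_10 carried unc-54 at 94670 CPM with lin-39 at 162.5 CPM, AS11 at 32410 with 25.1 CPM and VC1_3_6 at 5112 with 1033 CPM, and the rank correlation over the 7 classes was 0.571. Reporter transcript and transcript of the gene itself cannot be told apart, because both would carry the same 3′ tag and the labels do not give the reporter's 3′ end, and no biological explanation was tested, because the libraries analysed have 1 genotype.

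The second pattern was the level of unc-17, cha-1 and cho-1, highest in VC. More UMIs per cell in VC do not account for the whole pattern, in levels that are already scaled to the UMIs of a class. Among cells with 1000 or more UMIs, the ratios of VC to the other classes had a median of 89.3% of those in all cells. Several of these ratios are imprecise, because cho-1 had 1 UMI each in AS and unnamed cluster 1, and unc-17 had 3 in unnamed cluster 2. For unc-17 the ratio of VC to unnamed cluster 1 was 138 in all cells and 162 among the deeper cells. No biological explanation was tested, since the wild-type libraries in the matrices are not among the samples analysed here, so the part that loss of UNC-3 plays stays open.

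The third pattern was unnamed cluster 3, which carries unc-4 and oig-1, genes otherwise abundant in VC and in VD. Its unc-4 level would need 60.3% of VC cells or RNA, and 14 abundant VC genes had a median of 14.7% of the level that this share needs, with 12 of them under 50%. Its oig-1 level would need 12.3% of VD cells or RNA, and 15 abundant VD genes had a median of 4.70% of the level needed, with 12 under 50%. Both mixtures are excluded as the whole cause. What the cluster corresponds to among the classes of animals with UNC-3 stays open, and no biological explanation was tested, because the libraries analysed have 1 genotype.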

How the results depend on the processing

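Library size scaling alone, leaving out the unnamed clusters, unc-25-rich cells or unc-54, and the limit of 10% on mitochondrial UMIs were added after the data were examined. For comparisons, gene lists, class shares and unc-3 levels, 140 values stayed within the limits set for a change, and 28 moved. For class shares and unc-3 levels the limit was the SD over the 3 libraries. Leaving out 1 of these libraries cannot move a mean that far, so those values were bound to stay and are no evidence of stability. The cause of the changes was not tested, except that fewer libraries leave fewer degrees of freedom. Without the replicate block, which pairs the classes of a library, 637 genes passed for DD against VD, 619 for AS, 695 for unnamed cluster 1, 708 for unnamed cluster 2 and 352 for unnamed cluster 3, in place of 1550, 964, 1117, 1090 and 566, while GABAergic against cholinergic neurons gave 2299 and VC 1138. DESeq2 called 966 genes for DD against VD. Leaving out each replicate gave 956 to 1387 genes for DD against VD, 633 to 754 for AS and 719 to 882 for unnamed cluster 2, each lowest without replicate 1, and 2767 to 3274 for GABAergic against cholinergic neurons. Gene lists past the threshold fell to 0 with an estimated correlation in every comparison but unnamed cluster 1, which kept 2. With fry, which tests a list against no change and not, as camera does, against other genes, they numbered 19 for GABAergic against cholinergic neurons, 2 for DD against VD, 14 for AS, 21 for VC, 20, 21 and 17 for unnamed clusters 1, 2 and 3, and with camera 12, 9, 2, 7, 11, 4 and 10. Without a replicate, list counts ran from 3 to 4 for AS, highest without replicate 2, and from 2 to 4 for unnamed cluster 2, lowest without replicate 3. Among cells with 1000 or more UMIs, the shares of VC, DD and VD were 12.8, 20.1 and 24.3%, and the VD mean rests on replicate 3, at 5.29% against 31.2 and 36.3% in replicates 1 and 2. For named genes, 6561 values kept direction and side, 600 kept direction but no longer passed, 19 newly passed and 22 changed sign. Changes of sign in GABAergic against cholinergic neurons were del-1 at 0.012 among cells with 1000 or more UMIs; mab-9 at -0.091, slo-2 at 0.13, unc-7 at 0.24 and cat-1 at 1.38 with VC left out; gta-1 at 0.046 and cat-1 at 0.064 with library size scaling. With equal weight to each class they were cat-1 at 1.37, hlh-3 at 1.47, mab-5 at 0.15 and del-8 at 0.73, and del-8 was at 0.090 with the unnamed clusters left out. Without a replicate cat-1 ran from -0.89 to 0.77, positive without replicate 2. In AS, cat-1 was at -0.68 with DESeq2 and ran from -0.62 to 0.82 without a replicate, negative without replicate 2. In unnamed cluster 2, unc-63 was at 0.022 with no low-count filter, at 0.013 with under 10% mitochondrial UMIs and from -0.20 to 0.34 without a replicate, acr-2 ran from -0.17 to 0.076, and lin-39 was at -0.038 with library size scaling. In unnamed cluster 3, nhr-31 ran from -0.88 to 0.046 without a replicate. The comparisons of A-type with B-type and of dorsal with ventral cholinergic classes were not run under any alternative, since no such cells were annotated. Simulated 2-fold changes were recovered least in unnamed cluster 3, for 45% of the genes so changed, all above a minimum mean count. It is the class with the fewest cells (145) and UMIs (157688).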

Other observations

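The tests of other splits in this part were chosen after the counts of genes were seen, and the subclass levels were chosen after their values were seen.

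Levels of Hox genes were read by annotated subclass, whose annotation rests on the same transcriptomes, and no test between subclasses was run. In AS the subclass AS4_8 carried lin-39 at 1575 ± 277 CPM (SD, n = 3 libraries) and AS2_3 carried ceh-13 at 731 ± 118.8 CPM. The gene mab-5 was at 610 ± 99.4 CPM in AS9_10 and at 459.9 ± 62.1 CPM in AS11. In VC the subclass VC1_3_6 carried lin-39 at 1033 ± 189 CPM and VC4_5 carried mab-5 at 738 ± 230 CPM. In the GABAergic classes VD12 carried mab-5 at 492 ± 171 CPM and VD8_11 at 378 ± 94.3 CPM, and DD4_5 carried it at 298 ± 28.6 CPM against 40.1 ± 15.9 CPM in DD2_3. VD13 carried egl-5 at 1627 ± 479 CPM from 21 UMIs. Transcripts of unc-17 within AS were highest in AS9_10, at 347 ± 85.1 CPM.

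Replicate 3 had no cell in 9 of 16 non-neuronal types and in 11 types with a neuron tag, of which the spermathecal-uterine junction or uterine toroid is no neuron by its name. Those 9 types held 2942 cells in replicate 1 and 2048 in replicate 2. Replicate 3 also had the lowest depth per motor neuron.

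Other splits of the class sums were counted for each comparison. For GABAergic against cholinergic neurons and for DD against VD, the 10 splits of the 6 sums are too few for a share under 0.05. The real split gave 3316 genes in the first and 1550 in the second, and was the only 1 of the 10 to give as many. The highest other split gave 0 in both, and 3 of the other splits parted as many pairs of a library as the real one. For the cholinergic classes a test of 1 class against all other sums, without weights by class, was run on 100 splits. The real split for VC gave 694 genes and was matched by 1 split, itself, with 166 the highest other. For AS the real split gave 128 genes and for unnamed cluster 1 it gave 154, and 2 of the 100 splits gave as many in each, the other with 166 genes being the one that sets unnamed cluster 2 apart. For unnamed cluster 2 (166 genes) and unnamed cluster 3 (62 genes) only 1 split, the real one, gave as many, and the highest other gave 0. Because the classes were annotated from the same transcriptomes, the real splits were bound to call more genes than splits that mix classes, so these counts do not tell whether chance can be excluded.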
